A study of Mus musculus with 10 samples.

How the data were processed

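The series holds 10 2-colour Agilent arrays of 1 design (074809, 62976 spots) on 3 slides, each slide scanned in 1 session. Per the labels, bone marrow cells of donor mice were transduced with retrovirus, embedded in methylcellulose without growth factors, and colonies were picked for RNA. RNA was extracted with the RNeasy Micro kit, and it was amplified and labelled with Agilent's Low Input Quick Amp kit, per the labels' protocols. The 4 Cdk6-/- and 4 Cdk6-K43M samples were each labelled with Cy5 and set against 1 pool of 4 wild-type samples in Cy3. The dye-swap array of each genotype held the pool of its 4 RNAs in Cy3 and the wild-type pool in Cy5. The labels say that RNA came from individual colonies and give no number of colonies, animals or cultures behind a sample.

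Intensity values of each spot and its local background were read from the scans with Agilent Feature Extraction 11.5.1.1, per the file headers. The same files hold Agilent's processed signal intensities, which were background subtracted and dye normalized by that software, per the file headers. A table of log2 values, loess normalized per its name, was deposited by the authors, and which background correction went into it is not given in the sources used here. The headers give mm9 as the assembly of the probes, and no coordinates are reported.

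Scanner intensities were analysed with limma 3.58.1 in R 4.3.3, with the package data.table (version 1.17.8) for reading. Median spot signals were used with median local background, because the files hold no mean spot signals. Background was corrected by normexp with an offset of 50, and loess was fitted within each array without control spots. Spots that the scanner software found not uniform were set to missing, which left 62 missing values, and the spots of a probe were averaged. Of 59305 non-control spots, 56605 probes resulted. Gene symbols came from RefSeq annotation of the GRCm38.p6 assembly by transcript accession, which matched 58.3% of the probes, and the rest were kept under their own identifiers. A probe was kept if it was well above background on at least 3 of 4 single-sample arrays of 1 genotype, or in the wild-type channel on at least 5 of 10 arrays. The brightest of a gene's 28177 kept probes stood for the gene, and 4886 genes had several. This left 22008 genes, of which 9011 had no symbol.

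Comparisons with wild type used linear models with empirical Bayes moderation on the log2 ratios of all 10 arrays, with a coefficient for each genotype, swapped arrays entered with reversed sign, and a dye term (7 residual and 2.94 prior degrees of freedom). The wild-type pool was taken as 1 control sample without spread of its own. The swapped pools hold RNA of the same samples, so these fits count it again in their residual spread, which may be too small. The genotypes were compared with each other on the 8 single-sample arrays, where pool and dye cancel (6 residual and 2.86 prior degrees of freedom). P-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. The median SE was 0.0728 in comparisons with wild type and 0.106 between the genotypes. The dye effect had a median size of 0.0638 (log2) and passed the threshold in 1432 genes (6.51%). Where a group was never well above background, the change is given as a bound from its background level. Where that bound lay above the fitted fold, which uses ratios within arrays and not levels per channel, no fold is given, a choice made after seeing the data.

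Gene lists were tested with limma's camera with a preset correlation between genes, adjusted over the 23 lists of a comparison, and again with the correlation estimated from the data. The lists are those named in the report, and each gave its count of genes past the threshold over all genes and adjusted over the list alone. Named genes followed a rule fixed before the data were examined: Cdk6, the 10 highest and 10 lowest changes with one sign on all arrays (between the genotypes, with groups that did not overlap), the 6 largest each way common to both genotypes, and up to 4 members of a list with the smallest p. Symbols that are clone or accession names were left out, and 3 genes that the rule names are not reported here. Members named only to complete a short count were chosen after their values were seen.

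The fit was tested on simulated data with the observed spreads between samples and a wild-type pool without any spread. Its rates against wild type therefore leave out false calls that the pool's own spread would add. Changes of 1.5, 2 and 4-fold were recovered in 77.6%, 92.5% and 100% of genes against wild type (10% of calls false) and in 59.7%, 85.1% and 97% between the genotypes (8% false). For changes common to both genotypes, 50 data sets without any change were drawn from combinations of the observed sample deviations against 1 shared pool, with 29.9% of the spread as independent technical noise.

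Alternatives fixed before the data were examined covered background correction, Agilent's processed signals, median centring in place of loess, the authors' deposited table, filters, probe choice, the dye term, a spread for the pool, slide and replicate blocks, variance models, array weights, a fold threshold, the estimated correlation and leaving out each sample. Leaving out a sample removed its own array only. The swapped array of its genotype's pool, which holds RNA of that sample, stayed in the comparisons with wild type. The slide block for gene lists, Cdk6 and the correlation, and all alternatives for named genes, were added after seeing the data. Log2 ratios from the deposited table correlated across probes with the recomputed ones at r of 0.99 to 0.994, with slopes of 1.08 to 1.12. Their medians in Cdk6-/- replicates 1 to 4 were -0.0131, -0.0131, -0.0121 and -0.0161, in Cdk6-K43M replicates -0.0158, -0.0116, -0.0143 and -0.000811, and in the swapped pools -0.00902 and -0.00983. Among the deposited values 68 cells in 2 columns held calendar dates in place of values and were treated as missing. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3.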

Results

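Gene expression was measured in mouse bone marrow cells that had been transformed with BCR-ABL, the fusion kinase of chronic myeloid leukaemia and of a form of acute lymphoblastic leukaemia, and that had grown into colonies in methylcellulose without growth factors. The cells were wild type, lacked CDK6 (Cdk6-/-) or carried Cdk6-K43M, a mutant CDK6 protein without kinase activity. CDK6 is a cyclin D-dependent kinase of the G1 phase of the cell cycle that also acts on transcription. There were 4 samples of each mutant genotype, and each was hybridised in Cy5 on its own 2-colour Agilent array against the same pool of wild-type RNA in Cy3. For each genotype, 1 further array held the pooled RNA of its 4 samples with the dyes exchanged, which gave 10 arrays in all. In the channel of the mutant genotype 46.9 to 49.9% of probes were well above background, in the wild-type channel 45.8 to 50%, and no spot was saturated. The number of arrays limits the precision of every value. Log2 ratios of mutant over wild type, compared across genes, correlated between samples of one genotype with Pearson's r of 0.329 to 0.594 in Cdk6-/- and 0.321 to 0.673 in Cdk6-K43M. Genes are not independent replicates. The series describes its samples as biological replicates, but nothing says that they came from separate animals or cultures. The p-values therefore measure only the spread between these samples. From the single samples and swapped pools, 29.9% of that spread was estimated to be technical. Whether the rest lies between animals, cultures or colonies is not known. The wild-type pool counted as 1 control sample, and its own spread is left out of every comparison with wild type. After the filter on dim probes 22008 genes were tested, of which 12997 had a symbol.

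Cdk6 itself was measured by 1 probe, which was well above background in both channels of all 10 arrays. Its log2 ratio to the wild-type pool in the Cdk6-/- samples was -0.37, -0.40, -0.18 and 0.0024 for replicates 1 to 4. It was -0.67 in the Cdk6-/- pool with exchanged dyes. In the Cdk6-K43M samples the ratio was 0.31, 0.40, 0.33 and 0.83, and 0.33 in the pool with exchanged dyes. The fitted Cdk6 level fell by 0.41 (log2, SE 0.0988, adjusted p = 0.0368) in Cdk6-/- and rose by 0.35 (SE 0.0988, adjusted p = 0.031) in Cdk6-K43M. The difference between the genotypes of 0.70 (SE 0.14, adjusted p = 0.089) did not pass the test. With Agilent's processed signals the changes were -0.975 and 0.708, and the decrease was -0.617 in the deposited table. Where the probe lies relative to the deleted part of the gene is not given in the sources used here, and a probe outside that part still reads the remaining transcript, so its level does not check the labels. The decrease in Cdk6-/- no longer passed with slide as a block (-0.41, adjusted p = 0.0727), without the swapped arrays and dye term (-0.24, adjusted p = 0.137), with standard errors widened for the spread of the pool (adjusted p = 0.267). It was also lost without Cdk6-/- replicate 1, 2 or 3 (adjusted p = 0.0964, 0.0826 and 0.0519). The increase in Cdk6-K43M no longer passed with widened standard errors (adjusted p = 0.179). The difference between the genotypes passed with Agilent's processed signals (1.63, adjusted p = 0.0317), with median centring (0.84, adjusted p = 0.0457) and with all 10 arrays in the fit (0.77, adjusted p = 0.0154). The fit of all 10 arrays counts the samples' RNA again through the swapped pools, as do the comparisons with wild type.

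The first comparison asked which transcripts differ when the whole CDK6 protein is missing. Genes of granulocytes and monocytes were among the largest decreases in Cdk6-/- colonies. S100a9, which pairs with S100a8 to form the calcium-binding protein calprotectin of neutrophils and monocytes, fell by 4.16 (log2, SE 0.13, adjusted p = 2.38e-07). S100a8 was at least 8.07-fold lower (adjusted p = 9.66e-07) and not well above background in any Cdk6-/- sample. Trf, which encodes the plasma iron carrier transferrin, fell by 3.39 (SE 0.126, adjusted p = 6.99e-07). Uchl1, a ubiquitin hydrolase typical of neurons, fell by 2.89 (SE 0.191, adjusted p = 5.14e-05). Ly86, the partner of a Toll-like receptor relative on B cells and macrophages, fell by 2.5 (adjusted p = 0.0266). Cd5l, a scavenger protein secreted by macrophages, fell by 2.05 (adjusted p = 0.037) and Lgals3, the lectin galectin-3, by 1.98 (adjusted p = 0.0463). The other genes among the 10 lowest were Clic6, a chloride channel protein (-2.36, adjusted p = 0.00139), Serpine2, a secreted protease inhibitor (-2.24, adjusted p = 0.000194), and Laptm4b, a lysosomal membrane protein (-2.11, adjusted p = 0.000194).

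The highest increase in Cdk6-/- was that of Ehd3, a protein of endocytic recycling, which rose by 3.05 (log2, SE 0.287, adjusted p = 0.000453) and was well above background in 5 of 10 wild-type channels. Pcdh17, a cell adhesion protocadherin, rose by 2.84 (SE 0.544, adjusted p = 0.0174, well above background in 2 of 10 wild-type channels), and Thy1, a surface glycoprotein of T cells, by 2.14 (adjusted p = 0.0179). Eaf2, which binds the transcription elongation factor ELL, rose by 2.35 (adjusted p = 0.00066) on its brightest probe, while its other kept probe had a mean of -0.43. Tlr6, a Toll-like receptor for bacterial lipopeptides, was at least 3.08-fold higher (adjusted p = 0.00066), since it was not well above background in the wild-type channel of any array. Such bounds set one channel against the other and are open to dye bias, because the dye swaps were not balanced. Fcrl6 (1.88, adjusted p = 0.000876), a receptor of the Fc receptor-like family, Nrxn2 (1.79, adjusted p = 0.000154), a synaptic adhesion protein, Klk8 (1.68, adjusted p = 0.026), a secreted serine protease, and Tmem59l (1.52, adjusted p = 0.034) were also among the 10 highest.

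Of the 23 gene lists fixed before the data were examined, 6 shifted as a whole in Cdk6-/- by limma's camera test with its preset correlation, all downwards, and none of these calls held with an estimated correlation. Among 39 measured p53 target genes, 17 fell, 1 rose and 21 did not pass (26 fell and 3 rose adjusted over the list alone). Its median was -0.33 (adjusted p = 1.92e-12, adjusted p = 0.0814 with an estimated correlation). Polk, a DNA polymerase that copies past lesions, fell by 0.54 (adjusted p = 0.00197), Ccng1, cyclin G1, by 0.53 (adjusted p = 0.00605), and the death receptor gene Eda2r was at least 1.52-fold lower (adjusted p = 0.00394). Pidd1, a scaffold of p53-induced cell death, fell by 0.49 (adjusted p = 0.00661) on its brightest probe, with 0.09 on its other probe. The p53 target that rose was Apaf1 (0.21), the apoptosome scaffold, named after its value was seen. Among 35 DNA replication and G1/S genes, 17 fell, none rose and 18 did not pass (28 fell adjusted over the list alone). The median of the list was -0.28 (adjusted p = 2.33e-14, adjusted p = 0.41 with an estimated correlation). Rrm2, the small subunit of ribonucleotide reductase, fell by 0.68 (adjusted p = 0.0033), and the replication licensing genes Mcm2 (-0.44, adjusted p = 0.00682), Cdc6 (-0.42, adjusted p = 0.013) and Mcm10 (-0.40, adjusted p = 0.0168) fell too. Among 30 mitotic genes 4 fell and 26 did not pass (5 fell adjusted over the list alone). The list median was -0.13 (adjusted p = 0.00342, adjusted p = 0.708 with an estimated correlation). They were Nek2 (-0.77, adjusted p = 0.000194), a kinase of centrosome separation, Birc5 (-0.32), the inhibitor of apoptosis survivin, Ccnb1 (-0.28), cyclin B1, and Prc1 (-0.24), a spindle midzone protein.

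Among 18 measured granulocyte, monocyte and macrophage markers, 7 fell in Cdk6-/-, none rose and 11 did not pass (13 fell adjusted over the list alone). Its median was -0.80 (adjusted p = 5.83e-22, adjusted p = 0.25 with an estimated correlation). Besides S100a9 and S100a8, the neutrophil granule gene Ngp was at least 1.28-fold lower (adjusted p = 0.00988), and Camp was lower (adjusted p = 0.0183) and not well above background in any Cdk6-/- sample. The list median was -1.37 with Agilent's processed signals and -0.47 without a filter on dim probes. Over the settings tried its adjusted p with the preset correlation rose to as much as 0.0406. Lower myeloid genes in the mutant cells and myeloid RNA in the single wild-type pool cannot be told apart here. Among 25 immediate early genes 5 fell and 20 did not pass (7 fell and 1 rose adjusted over the list alone). The median of the list was -0.15 (adjusted p = 2.95e-05, adjusted p = 0.445 with an estimated correlation). Klf2, a transcription factor of lymphocyte quiescence, fell by 1.69 (adjusted p = 1.25e-05), Btg2, an anti-proliferative p53 target, by 0.70 (adjusted p = 0.0141), Myc by 0.45 (adjusted p = 0.0255) and Ier5 by 0.35 (adjusted p = 0.0109). The last of the 5 was Egr3 (-0.38), named after its value was seen. Of the 5 genes linked to CDK6 as a transcriptional regulator 1 fell, the receptor tyrosine kinase gene Flt3 (-0.54, adjusted p = 0.0322), and 4 did not pass (4 fell adjusted over the list alone). The list median was -0.34 (adjusted p = 0.0278, adjusted p = 0.242 with an estimated correlation). The cell cycle inhibitor locus Cdkn2a had -0.66 (adjusted p = 0.0842), the growth-response transcription factor gene Egr1 -0.33 (adjusted p = 0.12) and Vegfa, which encodes an angiogenic growth factor, -0.27 (adjusted p = 0.123, with 1 of its 4 probes at 0.08).

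The other lists did not pass the camera test in Cdk6-/-. Of 25 CDK, cyclin, CDK inhibitor and RB family genes (median -0.06, adjusted p = 0.266), E2f5 (0.43) and E2f6 (0.45) rose and 4 fell, namely Cdkn1a (-0.80), which encodes the inhibitor p21, E2f7 (-0.46, with 1 of its 2 probes at -0.0429), and, named after their values were seen, E2f8 (-0.75) and Rb1 (-0.35), the retinoblastoma gene. Adjusted over the list alone, 3 rose and 6 fell. Of 14 BCL2 family genes (median -0.025, adjusted p = 0.155, and median 0.016 with median centring) 4 fell, namely Pmaip1 (-1.42), Bmf (-0.95, with 1 of its 2 probes at -0.169), Bbc3 (-0.63) and Bax (-0.48). Adjusted over the list alone, 5 fell and 1 rose. Of 16 STAT5 and cytokine-signalling targets (median -0.08, adjusted p = 0.266) the feedback inhibitors Socs2 (-0.39) and Cish (-0.37) fell, with 3 lower and 1 higher adjusted over the list alone. Of 14 NF-kappaB and inflammatory genes (median -0.07, adjusted p = 0.155) Tnf (-0.80) and Cd83 (-0.57, well above background in 1 of 4 Cdk6-/- samples) fell, with 6 lower and 1 higher adjusted over the list alone. Of 26 interferon response genes (median 0.21, adjusted p = 0.13) the immunoproteasome subunit Psmb8 (0.31) rose. Of 27 B-lineage progenitor markers (median 0.13, adjusted p = 0.139) Igll1 (0.38), the surrogate light chain, and Bcl11a (0.39, with 1 of its 3 probes at -0.20) rose, with 5 higher and 1 lower adjusted over the list alone. Ribosome biogenesis and MYC target genes (20 measured, median -0.06, adjusted p = 0.155) had 2 lower, Myc and Odc1 (-0.36), the first enzyme of polyamine synthesis. Stress response genes (17 measured, median -0.15, adjusted p = 0.155) had 1 lower, the chaperone Hspa5 (-0.42), with 6 lower and 1 higher adjusted over the list alone. Of 20 glycolysis and hypoxia genes (median 0.06, adjusted p = 0.495) Car9 rose (0.28, with 1 of its 2 probes at -0.020), and none of 17 cholesterol synthesis genes passed (median 0.08, adjusted p = 0.495). Some of these lists passed in other settings, all with the preset correlation, while no list passed with an estimated one in the main fit. Without a filter on dim probes they were the BCL2 family (adjusted p = 0.0329), interferon (adjusted p = 0.0279) and B-lineage lists (adjusted p = 0.0475), and without the swapped arrays and dye term the CDK and cyclin list (-0.127, adjusted p = 0.0499) and the ribosome biogenesis list (-0.208, adjusted p = 0.00943). The interferon list passed without Cdk6-/- replicate 3 (0.327, adjusted p = 0.0202) or Cdk6-K43M replicate 4 (0.251, adjusted p = 0.014), and without Cdk6-/- replicate 4 the ribosome biogenesis (-0.115, adjusted p = 0.00443) and B-lineage lists (0.175, adjusted p = 0.0419) passed.

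Among the markers of other cell types in Cdk6-/-, Cd74, the invariant chain, fell by 1.32 (adjusted p = 0.0213) while the other 8 MHC class II genes did not pass. The list had a median of 0.04 and a mean of -0.24 (adjusted p = 0.553). Of 10 T and NK cell markers Thy1 and Lck (0.54) rose and Cd2 (-1.19) and Tcf7 (not well above background in any Cdk6-/- sample) fell. The list had a median of -0.0059, a mean of 0.17 and a median of 0.0047 without background correction and 0.03 with median centring (adjusted p = 0.686). Gfi1b (1.06), a transcription factor of erythroid and megakaryocyte cells, rose among 6 such markers, whose median was 0.07 and mean -0.08 (adjusted p = 0.553), with 3 higher and 1 lower adjusted over the list alone. Of 10 stem and progenitor cell markers (median -0.14, adjusted p = 0.376) Flt3 fell. No gene passed among 3 mast cell and basophil markers (median -0.07, adjusted p = 0.495), 4 stromal and endothelial markers (median -0.018, mean 0.04, and median 0.0045 with median centring; adjusted p = 0.747) or 4 sex-linked genes (median -0.26, adjusted p = 0.78). The sex-linked median was -1.04 in replicate 2 against 0.0276 to 0.0521 in the other 3 samples. Over the settings tried, medians took both signs for glycolysis and hypoxia (-0.036 to 0.17), cholesterol synthesis (-0.099 to 0.159), MHC class II (-0.0263 to 0.0627), erythroid (-0.0197 to 0.334) and sex-linked genes (-0.581 to 0.0352).

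In all, 1593 of the 22008 genes (7.24%) passed limma's moderated test in Cdk6-/- with Benjamini-Hochberg adjustment, 745 higher and 848 lower, and 1419 of them had one sign on all of the genotype's arrays. These arrays share the wild-type pool, so one sign on all of them is no independent support. At least 2-fold changes numbered 120, of which 40 were higher and 80 lower. The called genes kept the sign of the overall change within slides 1, 2 and 3 in 99.1%, 99% and 97.3% of cases, which the calls themselves favour. With slide as a block and the preset correlation (no list passed with an estimated one without the block) the list medians were -0.31 for p53 targets (adjusted p = 1.31e-12), -0.26 for DNA replication (adjusted p = 6.94e-12), -0.29 for the CDK6-linked genes (adjusted p = 0.0206), -0.14 for immediate early genes (adjusted p = 4.52e-06) and -0.77 for myeloid markers (adjusted p = 2.96e-21). The mitotic list no longer passed (-0.08, adjusted p = 0.085). Within slides, the p53 target median was -0.51 in replicate 1 on slide 1, -0.45 and -0.40 in replicates 3 and 4 on slide 2, and -0.39 in replicate 2 on slide 3, and the DNA replication median was -0.46, -0.49 and -0.18, and -0.34 in that order. The count of changed genes was 638 with slide as a block (602 of them among the 1593), 130 with standard errors widened for the pool's spread, 612 and 951 without Cdk6-/- replicate 1 and 2, and 802 with median centring (509 higher, 293 lower). It was 3292 without the swapped arrays and the dye term and 6900 with array weights. The CDK6-linked list did not pass with Agilent's processed signals (adjusted p = 0.069), without Cdk6-/- replicate 1 (adjusted p = 0.0565) or without Cdk6-K43M replicate 2 (adjusted p = 0.055).

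**Figure D1:**
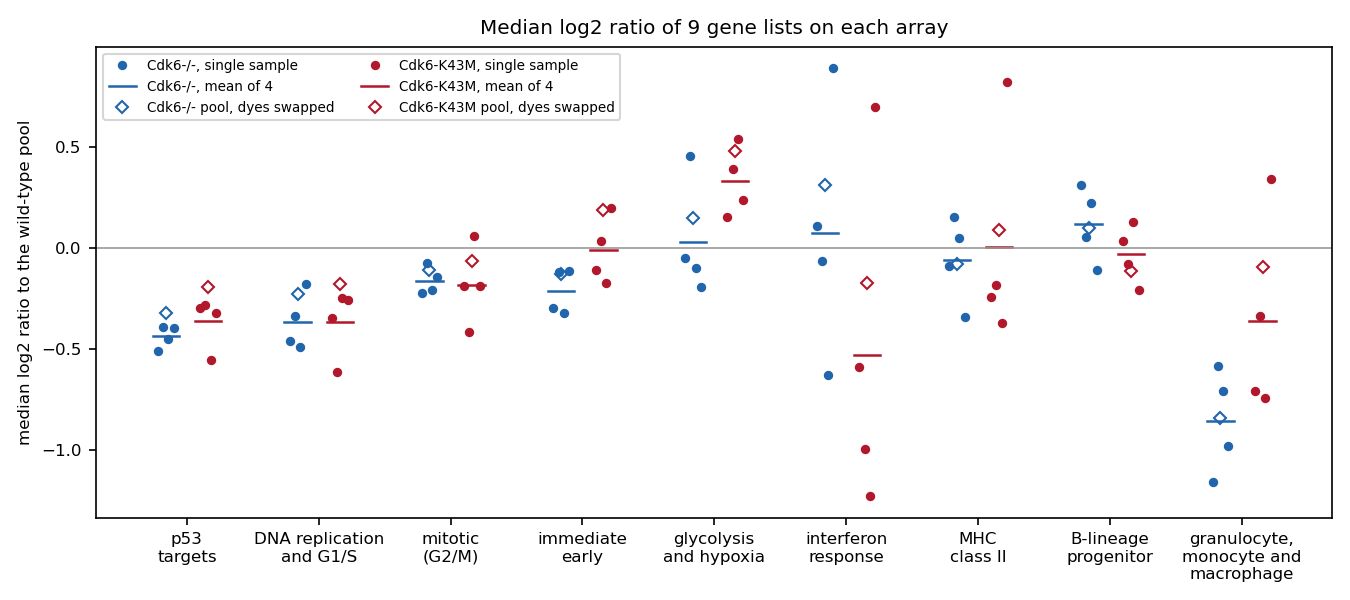
Median log2 ratio of mutant over wild-type pool (vertical axis) for 9 gene lists (horizontal axis), with dots for the 4 single samples of Cdk6-/- and of Cdk6-K43M, bars for their means and diamonds for the pools with exchanged dyes. The p53 target medians lay between -0.56 and -0.28 in all 8 samples, while interferon response medians ranged from -1.23 to 0.89. All ratios share 1 wild-type pool, so a sign common to all samples may come from the pool. With median centring in place of loess the Cdk6-K43M medians of DNA replication, mitotic and myeloid genes turned to values above 0. The median of all genes lay above 0 there too. Of these lists only the mitotic one then lost its call with the preset correlation, and with loess none passed with an estimated one.

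The second comparison asked which transcripts differ when the protein is present without its kinase activity. The calprotectin genes and transferrin were also the lowest in Cdk6-K43M colonies: S100a9 fell by 3.94 (log2, SE 0.13, adjusted p = 2.99e-07), Trf by 3.45 (SE 0.126, adjusted p = 4.66e-07) and S100a8 by 2.94 (SE 0.126, adjusted p = 1.7e-06), a value limited by the background, since S100a8 was well above it in 1 of the 4 samples. Ly6d, a marker of early B-lineage commitment, fell by 2.80 (SE 0.279, adjusted p = 0.000247), Fcrla, an intracellular Fc receptor-like protein of B cells, by 2.70 (adjusted p = 0.000473), and Ms4a1, which encodes CD20, by 2.67 (adjusted p = 0.00138). Ly86 fell by 2.83 (adjusted p = 0.00579), Laptm4b by 2.19 (adjusted p = 8.35e-05) and the serine protease inhibitor gene Serpina3f by 2.16 (adjusted p = 0.00377). Mtus2, a microtubule-associated protein, was lower (adjusted p = 0.0209) and not well above background in any Cdk6-K43M sample.

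Gbp2b, an interferon-inducible guanylate-binding protein, had the highest increase in Cdk6-K43M, rising by 4.62 (log2, SE 0.453, adjusted p = 0.000222). Tmem40, a transmembrane protein, rose by 3.58 (SE 0.231, adjusted p = 2.07e-05), Thy1 by 2.79 (adjusted p = 0.00171) and Pcdh17 by 2.63 (adjusted p = 0.0084, with the same 2 of 10 wild-type channels well above background). Ankrd37, a target of hypoxia-inducible factor, rose by 2.58 (adjusted p = 0.000947). Rdh10, an enzyme of retinoic acid synthesis, rose by 2.53 (adjusted p = 0.00173), Pomgnt2, a glycosyltransferase that acts on dystroglycan, by 2.5 (adjusted p = 2.33e-05) and Ifitm1, an interferon-induced membrane protein, by 2.42 (adjusted p = 0.0255). Scn4b, a sodium channel subunit, rose by 2.01 (SE 0.0855, adjusted p = 1.7e-06), and Fam183b, a gene linked to cilia, was higher (adjusted p = 0.000109) and not well above background in the wild-type channel of any array.

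In Cdk6-K43M 5 of the 23 lists shifted by the camera test with its preset correlation, none of them with an estimated correlation. Among 39 p53 target genes 20 fell, 2 rose and 17 did not pass (24 fell and 2 rose adjusted over the list alone). Its median was -0.30, and -0.19 with median centring (adjusted p = 3.33e-05, adjusted p = 0.467 with an estimated correlation). The pro-apoptotic gene Bbc3 (PUMA) fell by 1.05 (adjusted p = 0.000727) and Dcxr, a xylulose reductase, by 0.53 (adjusted p = 0.000906), whereas the kinase gene Plk3 rose by 0.75 (adjusted p = 0.000176) and Apaf1 by 0.38 (adjusted p = 0.000535, with -0.10 on its other probe). Among 35 DNA replication and G1/S genes 19 fell, none rose and 16 did not pass (23 fell adjusted over the list alone). The median of the list was -0.25 (adjusted p = 6.47e-08, adjusted p = 0.804 with an estimated correlation). It turned to 0.0013 with median centring, where the median of all genes was 0.11. The list still passed downwards there with the preset correlation (adjusted p = 0.00233). Rrm2 fell by 0.68 (adjusted p = 0.000941), Pola1, the catalytic subunit of DNA polymerase alpha, by 0.58 (adjusted p = 0.00296), the clamp loader subunit Rfc3 by 0.45 (adjusted p = 0.00338) and Rpa2, which binds single-stranded DNA, by 0.32 (adjusted p = 0.0025). Among 30 mitotic genes 8 fell, 1 rose and 21 did not pass (the same counts adjusted over the list alone). The list median was -0.10 that turned to 0.10 with median centring (adjusted p = 0.0169, adjusted p = 0.908 with an estimated correlation). Nek2 fell by 0.97 (adjusted p = 2.21e-05), Ccnb1 by 0.49 (adjusted p = 0.00184) and Prc1 by 0.33 (adjusted p = 0.00531, with 1 of its 2 probes at 0.11), while Tpx2, a spindle assembly factor, rose by 0.27 (adjusted p = 0.0159). Without the swapped arrays and dye term the medians were -0.376 for DNA replication and -0.194 for mitotic genes.

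Glycolysis and hypoxia genes moved the other way in Cdk6-K43M: 9 of 20 rose, 1 fell and 10 did not pass (13 rose and 1 fell adjusted over the list alone). Its median was 0.43, and 0.739 with median centring (adjusted p = 3.33e-05, adjusted p = 0.804 with an estimated correlation). Besides Ankrd37, the glucose transporter gene Slc2a1 rose by 0.93 (adjusted p = 0.00132), Ero1a, an oxidase of disulfide formation, by 0.57 (adjusted p = 0.00184) and the carbonic anhydrase gene Car9 by 0.33 (adjusted p = 0.00409), while Vegfa fell by 0.53 (adjusted p = 0.00515, with 1 of its 4 probes at 0.06). Among 18 granulocyte, monocyte and macrophage markers 6 fell, none rose and 12 did not pass (the same counts adjusted over the list alone). The median of the list was -0.14 (adjusted p = 3.96e-08, adjusted p = 0.908 with an estimated correlation). It turned to 0.021 with median centring, where the list still passed downwards with the preset correlation (adjusted p = 4.52e-12). The list median was -0.217 with Agilent's processed signals, -0.346 without Cdk6-K43M replicate 4 (adjusted p = 7.59e-17 with the preset correlation), -0.074 without replicate 1 and -0.0521 without replicate 3. The swapped pool, which holds RNA of the sample left out, stayed in these fits. Camp and Mpo, genes of neutrophil granules, were lower (adjusted p = 0.000691 and 0.00264) and not well above background in any Cdk6-K43M sample. Cdk6-K43M replicate 4 stood apart in this list, with a median of 0.34 against -0.74 to -0.34 in the other 3 samples, and macrophage genes were high in it, among them the lysozyme gene Lyz2 at 2.24 against a mean of -0.43 in the other 3 and the colony-stimulating factor receptor gene Csf1r at 1.95 against -0.75. In the same sample the medians of interferon response genes (0.70 against -1.23 to -0.59) and MHC class II genes (0.82 against -0.37 to -0.18) were high as well.

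Several further lists held many changed genes in Cdk6-K43M without passing the camera test, and most of their medians changed sign with median centring. Of 27 B-lineage progenitor markers 5 rose, 7 fell and 15 did not pass (9 rose and 10 fell adjusted over the list alone; median -0.07, and 0.27 with median centring; adjusted p = 0.87). Rag2 rose by 1.14 (adjusted p = 0.00316), and, named after their values were seen, Rag1 (0.77), Dntt (0.68), Il7r (0.62) and Ebf1 (0.40) rose as well. Rag1, Rag2 and Dntt act in immunoglobulin gene rearrangement. Besides Ms4a1, the B cell genes Cd79b (-0.51, adjusted p = 0.000956), a chain of the B cell receptor, and Pou2af1 (-0.60, adjusted p = 0.00117), a transcriptional coactivator, were among the 7 that fell, and the rest of these are not named. Of 25 CDK, cyclin, CDK inhibitor and RB family genes (median -0.09, and 0.07 with median centring; adjusted p = 0.984) 5 rose and 5 fell, with 5 and 6 adjusted over the list alone. Cdk8 (0.58), E2f6 (0.51) and E2f5 (0.34) rose and E2f8 (-1.30) fell, and, named after their values were seen, the cyclin D1 gene Ccnd1 (1.45) and Cdk7 (0.22) rose and Cdkn2d (-0.38), Rb1 (-0.38), E2f7 (-0.30) and Rbl2 (-0.27) fell. Of 14 BCL2 family genes (median -0.10, and 0.15 with median centring; adjusted p = 0.87) Bid (0.68) and Bok (0.68, named after its value was seen) rose and Bmf (-1.45, with 1 of its 2 probes at -0.0572), Pmaip1 (-1.18, named after its value was seen), Bbc3 (-1.05) and Bax (-0.45) fell. Of 25 immediate early genes (median 0.03, adjusted p = 0.901) Ier2 (0.54), Klf6 (0.51), Dusp1 (0.46) and Jund (0.24) rose and Klf2 (-1.09), Nr4a1 (-1.32) and Btg2 (-0.57) fell, where Jund, Nr4a1 and Btg2 were named after their values were seen. Of 17 stress response genes (median -0.17, mean 0.05, and median 0.11 with median centring; adjusted p = 0.901) Trib3 (1.51) and Chac1 (1.15), targets of the amino acid response, rose, and Hspa1b (-0.49), Sesn2 (-0.46), Hspa5 (-0.39) and Hsph1 (-0.35) fell, the last pair named after their values were seen. Adjusted over the list alone, 3 BCL2 family genes rose and 4 fell, 4 immediate early genes rose and 4 fell, and 3 stress response genes rose and 6 fell.

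Among the remaining lists in Cdk6-K43M, Lif (0.41) rose and Socs2 (-0.90) and Cish (-0.39) fell of 16 STAT5 and cytokine-signalling targets (median -0.12, and 0.07 with median centring; adjusted p = 0.339). Tnfaip3 (1.08), an inhibitor of NF-kappaB, rose and Relb (-0.78), Nfkb2 (-0.49) and Birc3 (-0.22) fell of 14 NF-kappaB genes (median -0.0025, mean 0.03, and median 0.14 with median centring; adjusted p = 0.773). Psmb8 (0.34) rose and Stat2 (-0.61, with 1 of its 2 probes at -0.091) fell of 26 interferon response genes (median -0.33, adjusted p = 0.466). With the preset correlation this list passed without Cdk6-K43M replicate 4 (-0.689, adjusted p = 0.00232) and with median centring (-0.314, adjusted p = 0.0214). In the main fit the estimated correlation gave an adjusted p of 0.908. Polr1b (0.55) and Nop2 (0.35) rose and Odc1 (-0.30, with 1 of its 2 probes at -0.0705) fell of 20 ribosome biogenesis and MYC target genes (median 0.09, adjusted p = 0.56). With median centring the median of this list was 0.345 (adjusted p = 0.0473 with the preset correlation, where the main fit gave 0.908 with an estimated one). Of 17 cholesterol synthesis genes 1 rose and 2 fell, Insig1 (-0.63) and Cyp51 (-0.62) (median 0.02, mean -0.0077; adjusted p = 0.901). Of the CDK6-linked genes only Vegfa passed (median -0.34, adjusted p = 0.297). H2-DMb1 (0.76) rose and Cd74 (-1.27) fell of 9 MHC class II genes (median -0.022, and 0.06 with median centring; adjusted p = 0.901). Thy1 and Tcf7 (0.31) rose and Cd2 (-1.32) fell of 10 T and NK cell markers (median 0.0087, and -0.018 with Agilent's processed signals; adjusted p = 0.721). Ly6a (1.60), which encodes the stem cell antigen Sca-1, and Procr (0.40) rose and Lmo2 (-0.90, with 1 of its 2 probes at -0.137) fell of 10 stem and progenitor cell markers (median 0.05, adjusted p = 0.901). No gene passed among 6 erythroid and megakaryocyte markers (median -0.0046, mean 0.017, and median 0.10 with median centring; adjusted p = 0.901), 3 mast cell and basophil markers (median -0.17, adjusted p = 0.901), 4 stromal and endothelial markers (median -0.10, mean 0.26; adjusted p = 0.901) or 4 sex-linked genes (median -0.07, and 0.025 with median centring; adjusted p = 0.901). Adjusted over the list alone, the counts differed in 4 of these lists: Stat2 no longer passed, 2 CDK6-linked genes fell, 3 T and NK cell markers rose, and 3 stem and progenitor cell markers fell. Medians in Cdk6-K43M also took both signs over the settings tried for immediate early (-0.0175 to 0.16), ribosome biogenesis (-0.0738 to 0.345), cholesterol synthesis (-0.117 to 0.229) and mast cell genes (-0.413 to 0.00461).

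In Cdk6-K43M 4427 of the 22008 genes (20.1%) passed the limma test, 2154 higher and 2273 lower, and 3872 of them had one sign on all of the genotype's arrays. The shared wild-type pool limits what one sign means here as well. At least 2-fold changes numbered 272, of which 149 were higher and 123 lower. The called genes kept the sign of the overall change within slides 1, 2 and 3 in 97.2%, 98.1% and 96.4% of cases, which the calls favour here too. With slide as a block 3701 genes passed. With the preset correlation (no list passed with an estimated one without the block) the blocked list medians were -0.30 for p53 targets (adjusted p = 3.62e-05), -0.26 for DNA replication (adjusted p = 1.81e-07), -0.10 for mitotic genes (adjusted p = 0.0124), 0.46 for glycolysis and hypoxia genes (adjusted p = 1.81e-07) and -0.11 for myeloid markers (adjusted p = 1.81e-07). Within slides, the glycolysis and hypoxia median was 0.15 in replicate 1 on slide 1, 0.39 and 0.24 in replicates 2 and 4 on slide 2, and 0.54 in replicate 3 on slide 3, and the p53 target median was -0.30, -0.28 and -0.32, and -0.56 in that order. The count was 1270 with standard errors widened for the pool's spread and 8329 with array weights, and with median centring 5594 genes were higher and 773 lower. The myeloid list did not pass with a stricter filter on dim probes (0.03, adjusted p = 0.971), and the mitotic list did not pass with median centring (adjusted p = 0.456) or without Cdk6-K43M replicate 2 (-0.054, adjusted p = 0.177).

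The changes common to both genotypes were then counted. In both genotypes 403 genes were higher and 567 lower, 970 in all, and 23 genes passed in opposite directions. Among those higher in both, Pcdh17, Thy1, Tlr6 (at least 3.14-fold in Cdk6-K43M, adjusted p = 0.00032), Nrxn2 (1.65 in Cdk6-K43M, adjusted p = 0.000103), Fcrl6 (1.61, adjusted p = 0.000726) and Rgcc, a regulator of the cell cycle (1.34 in Cdk6-/-, adjusted p = 0.00142, and 1.57 in Cdk6-K43M, adjusted p = 0.000204), had the largest changes. Among those lower in both they were S100a9, Trf, S100a8, Ly86, Laptm4b and Fcrla (-1.97 in Cdk6-/-, adjusted p = 0.00752). Lists drawn independently of each other would share 72.9 higher and 87.6 lower genes. Across genes, which are not independent replicates, the changes correlated with Pearson's r of 0.534 and Spearman's rho of 0.45. In 50 draws of unchanged groups against 1 shared pool, r had a median of 0.413 (5th to 95th percentile -0.094 to 0.764), the number of genes called the same way had a median of 0 and a highest value of 16, and the covariance had a median of 0.00964 (95th percentile 0.0273, highest 0.0551) against the observed 0.0392. In the same draws the count of changed genes had a median of 0 in both genotypes but a 95th percentile of 1210 and a highest value of 6490 for Cdk6-/-, and 1390 and 2380 for Cdk6-K43M. The pool cannot be divided, and part of the excess over these values may come from the shared pool. The number changed the same way was 447 with slide as a block, 102 with standard errors widened for the pool's spread, 440 and 600 without Cdk6-/- replicate 1 and 2, 542 with median centring (366 higher, 176 lower), 2208 without the swapped arrays and the dye term and 3466 with array weights. Of 3434 genes that passed in Cdk6-K43M and not in Cdk6-/-, 76 differed between the genotypes by their own test, and of 600 that passed only in Cdk6-/-, 12 did.

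**Figure D2:**
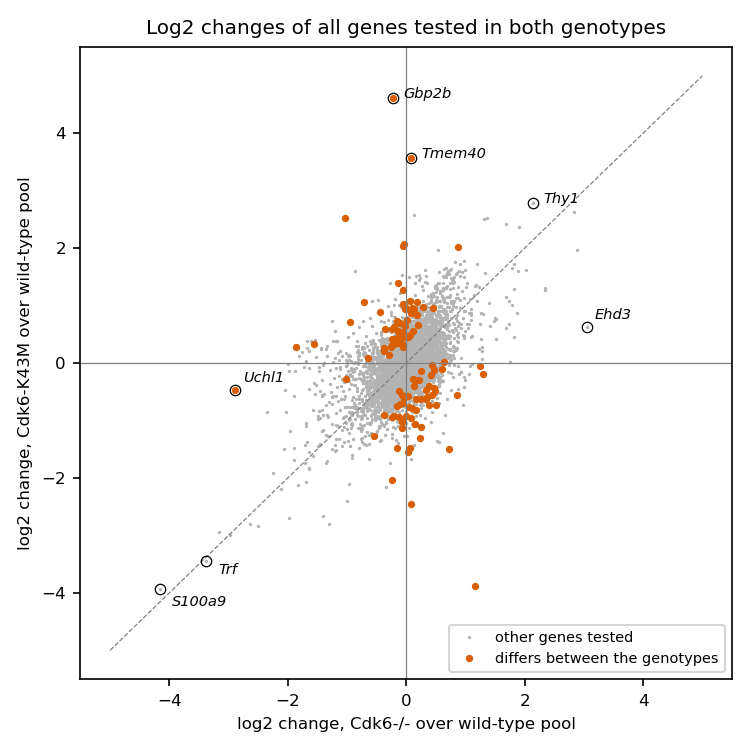
Log2 change in Cdk6-/- (horizontal axis) and in Cdk6-K43M (vertical axis) against the wild-type pool for each of 22008 genes, with the 113 genes that differed between the genotypes in orange and 7 named genes circled. S100a9 (-4.16 and -3.94) and Trf (-3.39 and -3.45) lie near the diagonal, while Gbp2b (4.62 in Cdk6-K43M) and Uchl1 (-2.89 in Cdk6-/-) lie far from it.

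The third comparison set both mutants directly against each other and asked which transcripts depend on whether the inactive kinase is present or the protein is missing. The wild-type pool and the dye cancel in this difference. Gbp2b was higher in Cdk6-K43M by 4.63 (log2, SE 0.652, adjusted p = 0.0247), Tmem40 by 3.48 (SE 0.341, adjusted p = 0.00446) and Uchl1 by 2.35 (SE 0.279, adjusted p = 0.0103). Fam183b (adjusted p = 0.0132) and Pianp, a ligand of an inhibitory leukocyte receptor (adjusted p = 0.00208), were higher too, and neither was well above background in any Cdk6-/- sample. Pir, an iron-binding nuclear protein (1.72, adjusted p = 0.0482), Gem, a small GTP-binding protein (1.33, adjusted p = 0.0292), Scn4b (1.14, adjusted p = 0.00802) and the orphan receptor gene Gprc5b (1.1, adjusted p = 0.0362) were also among the 10 highest. Gbp2b, Pir and Gprc5b were each well above background in 1 of the 4 Cdk6-/- samples, so the sizes of their differences are limited by the background.

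Lower in Cdk6-K43M than in Cdk6-/- were Cand2, a regulator of cullin ubiquitin ligases (-1.81, SE 0.212, adjusted p = 0.00989, well above background in 1 of 4 Cdk6-K43M samples), the methyltransferase-like gene Mettl23 (-1.55, SE 0.123, adjusted p = 0.00159), the MHC class I gene H2-Q5 (-1.49, adjusted p = 0.0103) and Trim12a, a gene of the tripartite motif family (-1.34, adjusted p = 0.00514). So were Slc39a11, a zinc transporter (-1.32, adjusted p = 0.00809), the pseudogene Pisd-ps3 (-1.29, adjusted p = 0.00651, with -0.0494 on its other probe) and Lrp6, a co-receptor of WNT ligands (-0.97, adjusted p = 0.00514, with -0.157 on its other probe). Thumpd1, an RNA-binding factor of tRNA acetylation, had the smallest adjusted p of these genes (-0.92, SE 0.0668, adjusted p = 0.00126). Apold1 was at least 2-fold lower (adjusted p = 0.00733), and Tox4 was lower on its brightest probe (-0.79, adjusted p = 0.0111) with 0.03 on its other probe.

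**Figure D3:**
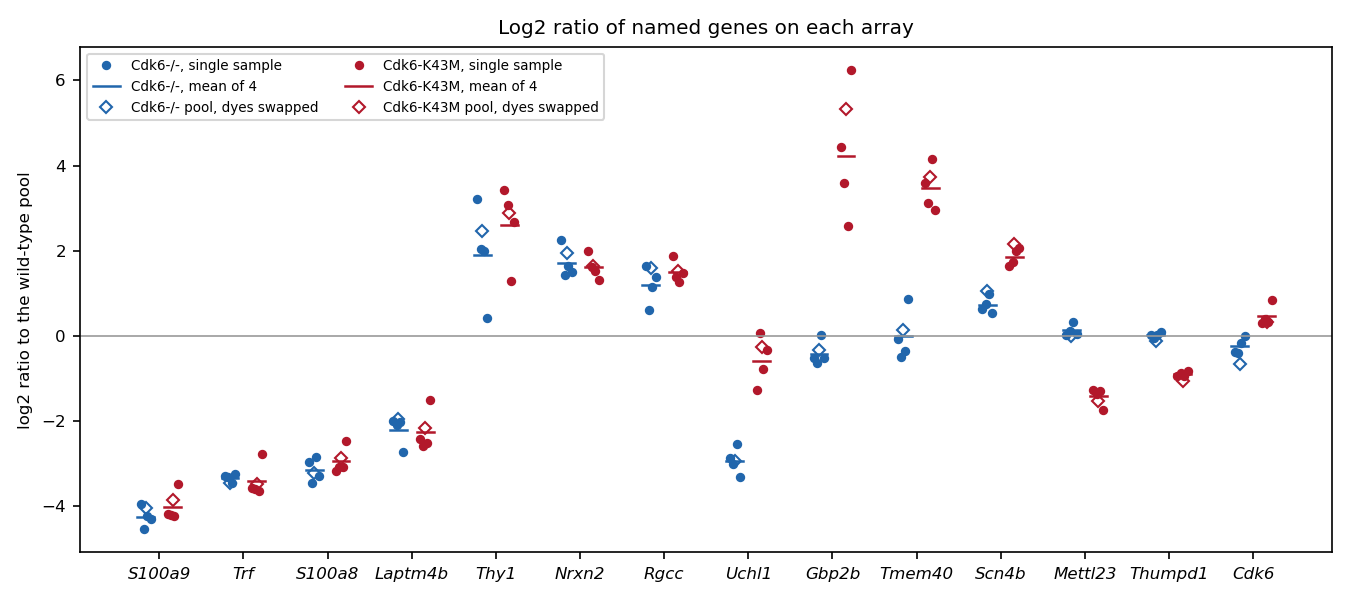
Log2 ratio of mutant over wild-type pool (vertical axis) for 14 genes (horizontal axis), with dots for the 4 single samples of each genotype and diamonds for the pools with exchanged dyes. S100a9, Trf, S100a8 and Laptm4b lie below 0 on every array, and Gbp2b and Tmem40 separate the genotypes. Every array holds the same wild-type pool, so a common sign may come from the pool.

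Of the 23 lists, 5 differed between the genotypes by the camera test with its preset correlation, none of them with an estimated correlation, although few single members passed. Immediate early genes were higher in Cdk6-K43M, 21 of 25 with a positive difference and a median of 0.18 (adjusted p = 6.24e-05, adjusted p = 0.919 with an estimated correlation). Ier2 was the 1 member that passed (0.66, adjusted p = 0.0441), and 5 were higher adjusted over the list alone: Ier2, Myc (0.67), Klf6 (0.65), Klf2 (0.61) and Jund (0.34), the last named after its value was seen. Glycolysis and hypoxia genes were higher, 17 of 20 with a positive difference and a median of 0.34 (adjusted p = 6.24e-05, adjusted p = 0.919 with an estimated correlation), with none past the threshold over all genes and 3 adjusted over the list alone: Ankrd37 (2.41), Slc2a1 (0.91) and Ero1a (0.50). Ribosome biogenesis and MYC target genes were higher, 18 of 20 with a positive difference and a median of 0.12 (adjusted p = 0.0135, adjusted p = 0.919 with an estimated correlation), with 1, Myc, adjusted over the list alone. Interferon response genes were lower, 2 of 26 with a positive difference and a median of -0.63 (adjusted p = 0.00361, adjusted p = 0.919 with an estimated correlation), with none past the threshold over all genes or adjusted over the list alone. Ifit3 had -1.31 (adjusted p = 0.366), Gbp2 -0.86 (adjusted p = 0.316) and Ddx58, which encodes the RNA sensor RIG-I, -0.52 (adjusted p = 0.295). B-lineage progenitor markers were lower, 7 of 27 with a positive difference and a median of -0.23 (adjusted p = 0.0318, adjusted p = 0.919 with an estimated correlation), and none passed. Blk, a SRC-family kinase of B cells, had -0.83 (adjusted p = 0.185) and Cd72 -0.98 (adjusted p = 0.256). Within slides 1, 2 and 3 the median differences were 0.19, 0.38 and 0.10 for immediate early genes, 0.20, 0.53 and 0.10 for glycolysis and hypoxia genes, 0.17, 0.21 and 0.07 for ribosome biogenesis and MYC target genes, -0.85, -0.30 and -1.30 for interferon response genes, and -0.22, -0.29 and 0.0090 for B-lineage markers.

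The other lists did not differ between the genotypes by the camera test. Plk3 was higher in Cdk6-K43M among 39 p53 target genes (0.77, adjusted p = 0.0201; list median 0.04, adjusted p = 0.478). Adjusted over the list alone, 1 more was higher, Ak1 (0.46). Tcf7, a transcription factor of T cells, was at least 1.39-fold higher among 10 T and NK cell markers (adjusted p = 0.047, list median 0.021, list adjusted p = 0.765). No gene passed among 18 myeloid markers (median 0.40, adjusted p = 0.164), where Lyz2 had 1.49 (adjusted p = 0.346) and replicate 4 of Cdk6-K43M carried the high macrophage genes. Over the settings tried the median of the myeloid list ranged from 0.0548 to 0.859. None passed among 10 stem and progenitor cell markers (median 0.16, adjusted p = 0.333), 17 stress response genes (median 0.019, adjusted p = 0.478), 25 CDK, cyclin, CDK inhibitor and RB family genes (median 0.04, adjusted p = 0.592), 9 MHC class II genes (median 0.12), 35 DNA replication genes (median 0.024), 5 CDK6-linked genes (median 0.21), 14 BCL2 family genes (median 0.04), 14 NF-kappaB genes (median 0.03) or 3 mast cell markers (median 0.15), the last 6 each at an adjusted p of 0.765. The same adjusted p of 0.765 held for mitotic genes (median -0.011), STAT5 targets (median -0.022, mean 0.024), cholesterol synthesis genes (median -0.04) and stromal markers (median -0.024, mean 0.19), whose medians were all above 0 with median centring. Erythroid and megakaryocyte markers (median -0.05, mean 0.07) and sex-linked genes (median 0.22, with a test statistic pointing down) had an adjusted p of 0.9. Adjusted over the list alone, Socs2 (-0.51) was lower and Bid (0.64), Trib3 (1.1) and Procr (0.68) were higher. Without Cdk6-K43M replicate 1 the cholesterol synthesis (-0.207, adjusted p = 0.0456), stress response (0.0439, adjusted p = 0.037) and myeloid lists (0.502, adjusted p = 0.0267) passed, and without Cdk6-K43M replicate 3 the mitotic (-0.0889, adjusted p = 0.0223) and myeloid lists (0.476, adjusted p = 0.0223). The myeloid list also passed without a filter on dim probes (0.194, adjusted p = 0.0233). All these calls used camera's preset correlation, and the estimated one gave an adjusted p of 0.919 for each of these lists in the main fit. Between the genotypes the medians of further lists took both signs over the settings tried. They were p53 targets (-0.0155 to 0.19), DNA replication (-0.0292 to 0.19), CDK and cyclin (-0.0254 to 0.154) and BCL2 family genes (-0.0563 to 0.221). NF-kappaB (-0.0774 to 0.208) and stress response genes (-0.0592 to 0.178) did so too, as did MHC class II (-0.0347 to 0.349), sex-linked (-0.107 to 0.647), erythroid (-0.337 to 0.0268), T and NK cell (-0.0268 to 0.108) and mast cell genes (-0.00686 to 0.314).

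Between the genotypes 113 of the 22008 genes (0.513%) passed the limma test, 58 higher and 55 lower in Cdk6-K43M, and 3095 had an unadjusted p under 0.05. Of the 113 genes 35 differed at least 2-fold. With slide as a block 33 genes passed, all of them among the 113, and the lists kept their calls with the preset correlation. None passed with an estimated correlation without the block (adjusted p = 0.919 each). The blocked adjusted p was 2.36e-05 for immediate early genes, 1.65e-07 for glycolysis and hypoxia genes, 0.0291 for ribosome biogenesis and MYC target genes, 0.00274 for interferon response genes and 0.0291 for B-lineage markers. Leaving out 1 sample gave 36 genes (without Cdk6-/- replicate 1) to 77 (without Cdk6-K43M replicate 2), Agilent's processed signals gave 73 and all 10 arrays with the dye term 559. The fit of all 10 arrays counts the samples' RNA again through the swapped pools, so its larger number adds no evidence. The comparisons with wild type, also on all 10 arrays, count that RNA again too. Without Cdk6-K43M replicate 4 the interferon median was -1.11 (adjusted p = 9.18e-14 with the preset correlation, where with all samples the estimated one gave 0.919) and the ribosome biogenesis and B-lineage lists did not pass (adjusted p = 0.142 each). The interferon list did not pass without Cdk6-/- replicate 4 (-0.401, adjusted p = 0.232) or Cdk6-K43M replicate 2 (-0.552, adjusted p = 0.0732) or 3 (-0.409, adjusted p = 0.115). Without Cdk6-/- replicate 3 neither the ribosome biogenesis list (0.0499, adjusted p = 0.343) nor the B-lineage list (-0.175, adjusted p = 0.337) passed. The B-lineage list lost its call in 6 of 16 settings, the others being Agilent's processed signals (adjusted p = 0.131), median centring (-0.0264, adjusted p = 0.455), the deposited table (adjusted p = 0.0532) and Cdk6-K43M replicate 2 left out (adjusted p = 0.0732). The ribosome biogenesis median was 0.22 without Cdk6-/- replicate 4, 0.177 without Cdk6-K43M replicate 3 and 0.313 with median centring, which also gave 0.31 for immediate early genes and 0.55 for glycolysis and hypoxia genes.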

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

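The tests of macrophage RNA, of an array fault, of neutrophils in the wild-type pool, of the pool's spread and of inherited chromosome stretches were chosen after the result was seen, and the tests of other splits, of a probe variant and of an exchanged sample before.

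In groups of 4 samples, Dixon's test at 95% marked 25 of 262 groups because 1 sample lay far from the other 3, where chance alone marks about 1 in 20 (13.1 here). In Cdk6-/- replicate 4 these were Laptm4b (-2.73 against -2.1 to -2), Ehd3 (1.46 against 3.29 to 3.62), Mcm2 (-0.318), Socs2 (-0.0196), Tap1 (0.658), Hsph1 (-0.103) and the BCL2 family median (-0.36). In Cdk6-/- replicate 2 they were Ccnb1 (-0.238), Kdm5d (-2.05) and the sex-linked median (-1.04), in replicate 1 Cdkn2a (-1.32), and in replicate 3 Psmb8 (0.00643), Ddx3y (0.38) and the NF-kappaB median (0.0966). In Cdk6-K43M replicate 4 they were S100a9 (-3.48 against -4.24 to -4.2), Trf (-2.78 against -3.65 to -3.59), S100a8 (-2.47 against -3.17 to -3.08), Laptm4b (-1.51), Vegfa (-0.836), Lmo2 (0.199) and the MHC class II median (0.822). In Cdk6-K43M replicate 3 they were Ly86 (-5.21 against -2.28 to -1.95), Cd79b (-0.514) and the p53 target median (-0.556), and in replicate 2 Eif2s3y (-5.29). The Kdm5d and Eif2s3y values were not well above background, and S100a8 was so in 1 of the 4 Cdk6-K43M samples, so these marks may depend on the background level.

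Both genotypes were set against the same pool, and their changes differed by the test between the genotypes (limma, adjusted p) in Gbp2b (4.63), Tmem40 (3.48), Uchl1 (2.35), Fam183b (2.03), Scn4b (1.14), Plk3 (0.769), Ier2 (0.657) and Tcf7 (0.52). Fam183b and Tcf7 were not well above background in any Cdk6-/- sample, so their fitted values are no measured size of change. Gbp2b was well above it in 1 of the 4 Cdk6-/- samples, so its value is limited by the background too. Of the gene lists, 5 differed by camera with its preset correlation and none with an estimated one (adjusted p = 0.919 each), with medians given for immediate early genes (0.183), glycolysis and hypoxia genes (0.338), ribosome biogenesis and MYC target genes (0.116), interferon response genes (-0.634) and B-lineage markers (-0.233). The 113 genes called between the genotypes were set beside all 35 splits of the 8 samples into 4 and 4. Only 1 split, the real one, called as many, and the highest other split called 1, which argues against a chance division of the samples.

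In Cdk6-K43M replicate 4 all 10 monocyte and macrophage genes measured stood above the other 3 samples (a share of 1), among them Lyz1 (2.62 against a mean of -0.823), Adgre1 (2.07 against -1.25) and Cd68 (1.76 against -0.811). That share restates the pattern and supports no explanation, so RNA of macrophages in this sample and expression of these genes by the transformed cells cannot be told apart. The array of the pooled RNA in swapped dyes showed a median of 0.912 of the expected rise, which argues against a fault of the array. In 57 of 59 genes called without this sample (0.966) it lay nearer to the other Cdk6-K43M samples, which argues against an exchange with a Cdk6-/- sample.

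The 6 genes with the largest decreases in both genotypes were S100a9, Trf, S100a8, Ly86, Laptm4b and Fcrla. With standard errors widened for the pool, S100a9, Trf, S100a8 and Laptm4b kept their calls in both genotypes (highest adjusted p = 0.00434, limma), while Ly86 (0.226 in Cdk6-/- and 0.0594 in Cdk6-K43M) and Fcrla (0.101 in Cdk6-/-) lost theirs. The genes were chosen for their size of change, so a spread of the pool as large as that of the samples stays open. Neutrophils in the wild-type pool could lower S100a9 and S100a8 in both genotypes, and the other neutrophil granule genes had medians of -0.333 in Cdk6-/- and -0.467 in Cdk6-K43M. Of these, Mpo, Ngp and Camp were not well above background in any mutant sample, so their fall is limited by the background, and Elane, which was, had -0.0821 and -0.109. Monocyte and macrophage genes lay below the pool as well, with Cdk6-/- means from -1.8 (Lyz1) to -0.546 (Fcgr3). In Cdk6-K43M without replicate 4 their means ran from -1.25 (Adgre1) to -0.199 (Fcgr3), while in replicate 4 most lay above the pool. Myeloid RNA in the pool and lower expression in the mutants cannot be told apart from these ratios. The explanation by neutrophils stays open, and no biological explanation was tested.

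Several genes that differed between the genotypes were close neighbours, such as Tmem40 and Cand2 on chromosome 6, and Gprc5b and Thumpd1 on chromosome 7 (order from GRCm38.p6). There were 8 pairs within 10 tested genes, against a median of 3 and a 95th percentile of 6 in 10000 random sets (one-sided permutation p = 0.0155). The top genes of other splits had a median of 4 pairs but reached 17. Stretches of chromosome inherited from another strain may leave such pairs, and the counts do not decide it. For a sequence variant under one probe, the bound set in advance against it was a median share of 0.5 of the difference on other probes. Over all 19 called genes with other probes the median share was 0.664, and 12 of the 19 reached 0.5. The 6 of these genes that were in pairs had a median share of 0.514, with 3 of the 6 below 0.5. Both medians met the bound against such a variant, but for the genes with low shares it stays open.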

How the results depend on the processing

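The slide block for gene lists, Cdk6 and the correlation, and all settings for named genes, were chosen after the result was seen. Agilent's processed signals gave 73 genes between the genotypes, 61 of them among the 113, and a Cdk6 difference of 1.63. Median centring gave 802 genes in Cdk6-/-, 542 common to both, a Cdk6 difference of 0.838 and 87.9% of the calls upwards in Cdk6-K43M against 48.7%, with an all-gene median of 0.112. Without swapped arrays and dye term there were 3292 genes in Cdk6-/- and 2208 common, and Cdk6 in Cdk6-/- was -0.239. Standard errors widened for the pool left 130, 1270 and 102 common genes, with Cdk6 at -0.411 and 0.355 no longer past the threshold, because the standard errors grew. The slide block gave 638 genes in Cdk6-/-, 33 between the genotypes and 447 common, with Cdk6 in Cdk6-/- at -0.415. Array weights gave 6900, 8329 and 3466 common genes. All 10 arrays gave 559 between the genotypes with a Cdk6 difference of 0.765, where the swapped pools count the same RNA again, as they do against wild type. At least 2-fold changes numbered 120, 272, 35 and 62 common. With an estimated correlation 0 lists passed in each comparison, from 6, 5 and 5. Other causes were not tested.

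Leaving out 1 sample gave 612 to 1931 genes in Cdk6-/-, 3592 to 4505 in Cdk6-K43M, 36 to 77 between the genotypes, 440 to 1.1e+03 common, a correlation of 0.487 to 0.593 and 3 to 8 lists between the genotypes. Cdk6 in Cdk6-/- then lay between -0.468 and -0.383. The swapped pools, which hold RNA of the sample left out, stayed in the comparisons with wild type. Counts without background correction (1430, 4271 and 108), from the authors' deposited table (1412, 4155 and 100), without a filter (1358, 4061 and 120), with a stricter filter (1453, 4242 and 89), with the mean of probes (1466, 4345 and 105) and with an intensity trend (1601, 4459 and 114) stayed within 1.5 times. Of 66 genes named for their size, 41 kept their call in every setting, 110 of 1345 values lost it and 0 reversed. Of 53 list results without a call over the 3 comparisons, 11 gained one in at least 1 setting (18 of 915). Ratios of dim genes are limited by background, since only 45.8 to 50% of the probes in an array's channel were well above it. The offset of 50 makes these ratios smaller too, as median green signals were 45 to 56.5 over backgrounds of 21 to 28.

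With the replicate number as a block 37 genes passed between the genotypes, 30 of them among the 113, and 2098 and 5078 passed against wild type. Samples with the same number correlated at 0.0839, -0.0659, 0.228 and 0.139 after removal of the genotype means, and Cdk6-/- replicates 3 and 4 correlated best with their own number but replicates 1 (0.201 with replicate 2) and 2 (0.105 with replicate 4) did not. Not every pair reached 0.1, so the numbers were not taken as pairs. The block changed the call of Cdk6 in no comparison, ended those of some named genes, Gbp2b, Tmem40 and Uchl1 between the genotypes among them, and was not run for gene lists or the correlation.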

Other observations

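The sex-linked values below were examined after the result was seen. Eif2s3y, a gene of the Y chromosome, had log2 ratios of -5.42 and -5.2 in Cdk6-/- replicates 2 and 3 and -5.29 in Cdk6-K43M replicate 2, where it was not well above background, and 0.0755, 0.102, 0.185, 0.141 and -0.0448 in the other samples. In the swapped pools it was -1.16 for Cdk6-/- and -0.748 for Cdk6-K43M. Kdm5d was low only in Cdk6-/- replicate 2 (-2.05 and -1.03 on 2 probes), where neither probe was well above background. Uty and Ddx3y, also of the Y chromosome, were well above background on every array, with 0.109, 0.000169 and -0.153 (Uty) and -0.0382, 0.38 and 0.0065 (Ddx3y) in the 3 samples with low Eif2s3y. Xist was not well above background on any array.

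Interferon response medians varied within genotypes: 0.108, -0.0648, -0.63 and 0.89 in Cdk6-/- replicates 1 to 4, and -0.59, -0.994, -1.23 and 0.697 in Cdk6-K43M. The swapped pools had 0.311 and -0.175.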
